A study of Nesterenkonia sp. AN1 with 4 samples.

How the data were processed

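RNA from 4 cultures of Nesterenkonia sp. AN1, 2 grown at 21 °C and 2 at 5 °C, was sequenced. Per the labels' protocols, total RNA was purified with a Direct-zol kit, depleted of ribosomal RNA with a Ribo-Zero kit and made into Illumina paired-end libraries. The aligner, its settings, the assembly version and the strand setting were not given in the sources used here. The series' design text calls the replicates biological, and the labels give no culture batch or date.

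All values came from 1 table of the whole series. The read counts in it, both total and unique gene reads, were deposited by the authors as whole numbers per feature without normalization, per the file headers. The RPKM values were deposited by the authors, and division of the total gene reads by feature length and by the summed gene reads gave them back for 100% of values within a relative tolerance of 1e-06. The normalized signal of the authors, headed as expression values per the file headers, held the same sorted values in each of the 4 columns, equal to the means of the ranked total reads, which is quantile normalization. The p-values deposited by the authors belong to an EDGE test with tagwise dispersions and to Baggerley's test, per the file headers, and the statistic of the latter is a score deposited by the authors. These comparisons of the authors were used only as a comparison with the calls made here. Lengths of 90.5% of the features were multiples of 3, so most feature lengths are coding lengths.

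The total gene reads entered edgeR 4.0.16 in R 4.3.3, with features kept by filterByExpr (2336 of 2796; 460 not tested, of which 3 had no read), TMM composition factors (1.10 and 0.955 at 21 °C, 1.01 and 0.943 at 5 °C), a design with temperature alone, and the quasi-likelihood test. p-values were adjusted by the Benjamini-Hochberg method over all tested features with a threshold of 0.05. The common biological coefficient of variation was 0.0637. With 2 libraries per group, p-values rest on a spread shared across genes, and they cover only the variation between these cultures. Normalised levels (CPM) used the composition-adjusted library sizes. Reads in the total but not in the unique gene reads were 0.155% to 0.227% of the gene reads. They lay in 84 features, none with a symbol among 35. The table gives no strand, so reads of overlapping or antisense features cannot be told apart. Reads are not independent molecules where amplification copied them, so 3 reads, the limit that a count of 0 allows, correspond to 8.33 to 10.0 CPM for counting error only.

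Each library held 291499 to 360195 gene reads. The test was run on simulated counts for this comparison with the real means and library sizes, in which 200 genes were changed. Each gene was given the common biological coefficient of variation of 0.0637, so differences in spread between genes were left out. That value came from the fit under test, so the rates below hold only for it and can be too favourable. Of the changed genes among 2249 tested, 68 of 97 with a 2-fold change (70.1%) and 39 of 94 with a 1.5-fold change (41.5%) were recovered, and 7 of 114 calls (6.14%) were false.

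The comparison, its test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named, per direction, up to 10 genes with the largest change among those past the threshold, with no overlap between groups, a mean of 50 or more reads and a known product, and the 2 largest without a known product. It also named every member of the lists of cold shock proteins and of RNA helicases and ribonucleases, and up to 2 called members per direction of each other list. The table gives no product names, so a symbol stood for a known product. The lists were written mostly as patterns of product names and matched 9 genes in 6 of 31 lists by symbol, missing genes such as pgk, eno, valS, ileS, guaA, fecE, ectC and rph. The patterns were therefore also matched to the usual product of each symbol, after the values were seen, which gave 24 genes in 15 lists. The list of cold shock proteins matched no feature, and that of RNA helicases and ribonucleases matched rph alone. The list with 4 or more tested members was tested with camera of limma, with a preset correlation of 0.01. The rule took 10 genes with symbols that rose and 4 that fell, and the other 21 genes with symbols were added after their values were seen, so that each of the 35 is reported. Ribosomal RNA genes were to be left out, but no feature is marked as one. All features were therefore kept, and any ribosomal RNA is in the main fit. The 2 features with the most reads, of 3122 and 1534 nt, were left out as an added alternative.

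Alternatives were DESeq2 1.42.0 size factors, upper-quartile scaling and no composition factor in the same fit; DESeq2's Wald test and limma-voom (limma 3.58.1); no filter and a minimum mean of 50 reads; an added 2-fold threshold; unique gene reads; limma on log2(RPKM + 1); and each library left out in turn. Limma on log2 of the quantile-normalized values with a pseudocount of 1, and the fit without the 2 features with the most reads, were added after the data were seen. Runs were defined as 5 or more consecutive tested features on a contig called in one direction. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.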

Results

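Gene expression was measured by RNA sequencing in Nesterenkonia sp. AN1, an actinobacterium isolated in Antarctica, grown at 21 °C or at 5 °C. Per the series' design text, 21 °C was taken as the optimal growth temperature and 5 °C as the cold condition, with 2 biological replicates at each. Each of the 4 libraries was deposited as a column of read counts over 2796 features of a draft genome in 42 contigs. The summed gene reads were 291499 and 360195 at 21 °C, and 356969 and 318686 at 5 °C. The median feature held 36.5, 38.5, 37 and 31 reads in these libraries, so counting error was large for many features. A pair of adjacent features on contig 19, at 239117 to 242238 and 242684 to 244217, took 13.8% and 26.2% of the gene reads at 21 °C and 14.7% and 19.9% at 5 °C. Contigs are numbered here by the last digits of their sequence names in the table, coordinates count from 1, and the assembly version and strand were not given in the sources used here.

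The comparison asked which genes differ in transcript level between growth at 5 °C and at 21 °C. Of the 2796 features, 35 carried a gene symbol in the table, and the other features carried only a locus identifier that the files do not pair with a product. The accounts of single genes therefore rest on those 35, with products stated as the usual ones for each symbol. Levels are TMM-normalised read counts scaled to a common library size (CPM), as mean ± SD (n = 2 libraries per temperature), and fold changes are given as 5 °C over 21 °C on the log2 scale ± SE. Fold changes come from the edgeR fit and can differ slightly from the ratio of the mean levels.

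Among the genes with symbols, 10 were higher at 5 °C, with each 5 °C library above both 21 °C libraries. Such separation adds little to a call: 450 of 451 features called higher and 472 of 472 called lower had it. Uncalled genes such as dnaK and kgd had it too. The GMP synthase gene guaA, on contig 23 at 142710 to 144290, rose 1.80-fold from 619.9 ± 51 to 1113 ± 88.2 CPM (0.85 ± 0.10, edgeR adjusted p = 1.35e-10). The phosphoglycerate kinase gene pgk, on contig 7 at 14022 to 15248, rose 1.82-fold from 349.95 ± 22.8 to 632.3 ± 52.4 (0.86 ± 0.12, edgeR adjusted p = 1.13e-08). The enolase gene eno, whose product also acts in lower glycolysis, rose 1.38-fold from 1122 ± 91.1 to 1546 ± 10.1 (0.46 ± 0.09, edgeR adjusted p = 4.33e-05). The glycerol kinase gene glpK rose 1.55-fold from 608.5 ± 94.5 to 942.9 ± 9.72 (0.64 ± 0.11, edgeR adjusted p = 9.76e-07). The phosphomannomutase gene manB rose 1.45-fold (0.54 ± 0.12, edgeR adjusted p = 0.000116). The elongation factor G gene fusA rose 1.40-fold from a high level, 3779 ± 229.9 to 5288 ± 534 CPM (0.48 ± 0.11, edgeR adjusted p = 0.000160). The gene of ribosomal protein S1, rpsA, rose 1.29-fold from 4278 ± 132 to 5533 ± 177 (0.37 ± 0.11, edgeR adjusted p = 0.00397). The gene of the proteolytic subunit of the Clp protease, clpP, rose by 0.46 ± 0.12, the purine synthesis gene purH by 0.36 ± 0.13, and the valyl-tRNA synthetase gene valS by 0.28 ± 0.10, with edgeR adjusted p of 0.00133, 0.0277 and 0.0165. guaA and pgk passed under each of the 15 alternative settings tested on single genes at an adjusted p under 0.05, but neither reached an added 2-fold threshold. Without a composition factor between libraries the calls of eno, fusA, clpP, rpsA, valS and purH ended, with log2 fold changes of 0.40, 0.41, 0.40, 0.30, 0.21 and 0.30 and edgeR adjusted p of 0.0544, 0.0962, 0.0640, 0.250, 0.361 and 0.225. The test on log2(RPKM + 1) ended the calls of the 8 genes other than guaA and pgk, with limma adjusted p from 0.0523 (glpK) to 0.421 (valS). On the quantile-normalized values fusA (0.17), rpsA (0.09), valS (0.15) and purH (0.32) lost theirs, with limma adjusted p of 0.0854, 0.124, 0.168 and 0.0941. DESeq2 ended the calls of clpP, valS and purH (adjusted p = 0.0936, 0.160 and 0.326), and a minimum mean of 50 reads those of valS and purH (edgeR adjusted p = 0.121 and 0.109). With a library left out, the call of clpP ended without replicate 1 at 21 °C (0.33, edgeR adjusted p = 0.0638) or replicate 2 at 5 °C (0.42, 0.0536). That of valS ended at nearly the same log2 fold change, 0.27 without replicate 2 at 21 °C and 0.28 without replicate 1 at 5 °C (edgeR adjusted p = 0.0684 and 0.0597). That of purH ended without replicate 1 at 21 °C (0.29, edgeR adjusted p = 0.190), and without replicate 1 (0.31, 0.181) or replicate 2 (0.44, 0.0534) at 5 °C.

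Another 7 genes with symbols were lower at 5 °C, again with no overlap between the libraries of the groups. The propionyl-CoA synthetase gene prpE, on contig 19 at 223347 to 225317, had the largest fall of these, 3.53-fold from 197.8 ± 43.2 to 55.4 ± 12.1 CPM (-1.82 ± 0.25, edgeR adjusted p = 7.16e-09). The ferric citrate transport ATPase gene fecE fell 1.80-fold from 166.3 ± 29.9 to 91.5 ± 15.9 (-0.85 ± 0.23, edgeR adjusted p = 0.00232). The gene of an aminotransferase of arginine synthesis, argD, fell 2.08-fold from 69.9 ± 0.603 to 33.7 ± 4.41 (-1.06 ± 0.39, edgeR adjusted p = 0.0230). These 3 genes averaged 42, 42.75 and 17 reads per library, below the minimum of 50 in the rule for named genes, and were chosen after their values were seen. The peptidoglycan precursor ligase gene murD fell 1.41-fold from 602.2 ± 30.5 to 424.8 ± 47.4 (-0.50 ± 0.12, edgeR adjusted p = 0.000463). Smaller falls were measured for the isoleucyl-tRNA synthetase gene ileS (-0.35 ± 0.13), the aspartate ammonia-lyase gene aspA (-0.27 ± 0.11) and the chaperonin gene groEL_1 (-0.25 ± 0.09), with edgeR adjusted p of 0.0222, 0.0419 and 0.0233. prpE kept its call with each library left out. The gene murD lost its call without replicate 2 at 5 °C (-0.38, edgeR adjusted p = 0.0578). The call of fecE ended without replicate 2 at 21 °C (-0.64, edgeR adjusted p = 0.0776) or replicate 2 at 5 °C (-0.68, edgeR adjusted p = 0.0902). Leaving out 21 °C replicates 1 and 2 and 5 °C replicates 1 and 2 in turn ended the calls of ileS (edgeR adjusted p = 0.152, 0.0510, 0.240 and 0.0748), argD (0.0923, 0.0944, 0.180 and 0.0705) and aspA (0.228, 0.0723, 0.310 and 0.112). That of groEL_1 ended without replicate 1 at 21 °C (0.158) or either 5 °C replicate (0.370 and 0.0553). In these fits the log2 fold changes ran from -0.38 to -0.26 for ileS, from -1.17 to -0.89 for argD and from -0.30 to -0.19 for aspA, and were -0.20, -0.14 and -0.31 for groEL_1. The calls of ileS, aspA and groEL_1 also ended without a composition factor (edgeR adjusted p = 0.0681, 0.129 and 0.155), although their log2 fold changes there were larger, -0.41, -0.33 and -0.32. Of the 7 genes only prpE kept its call in DESeq2, where the adjusted p was 0.0856 for murD, 0.139 for fecE, 0.266 for argD, 0.346 for ileS, 0.381 for aspA and 0.178 for groEL_1. The test on log2(RPKM + 1) ended the calls of murD, argD, ileS, aspA and groEL_1 (limma adjusted p = 0.0513, 0.0695, 0.283, 0.202 and 0.186), and the quantile-normalized values that of argD (0.0907). The fit without a filter ended those of groEL_1 (edgeR adjusted p = 0.0613) and aspA (0.0934), and DESeq2 size factors that of aspA (0.0552).

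**Figure D1:**
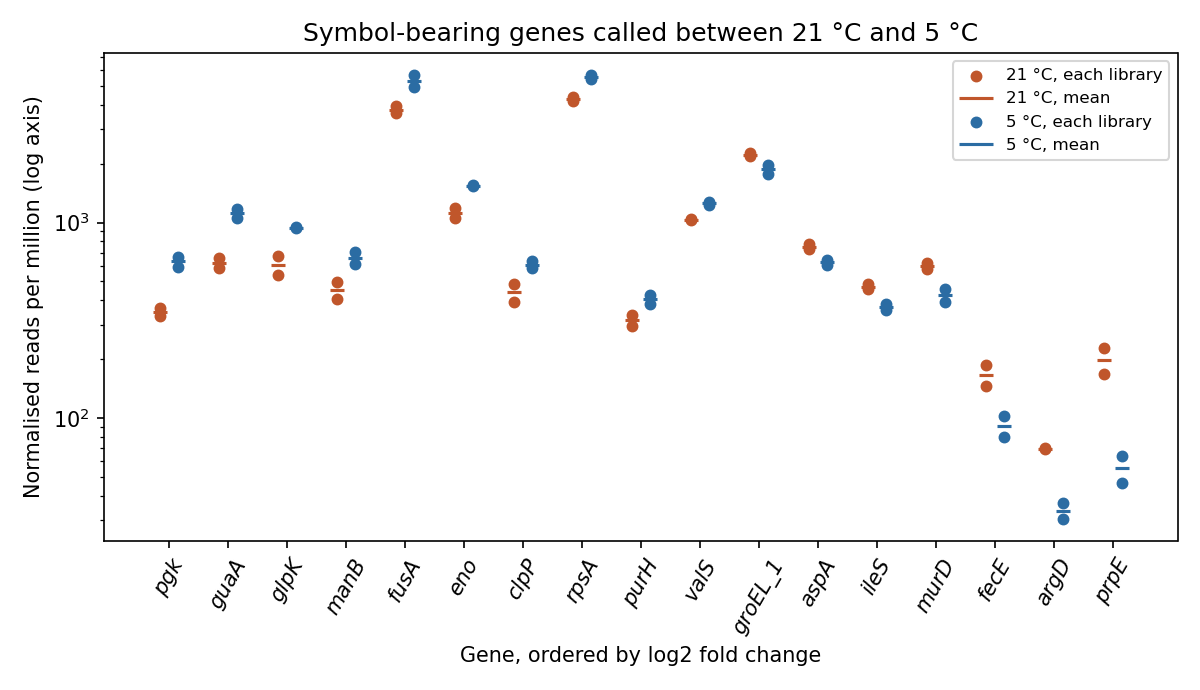
Normalised read counts (CPM) on a log axis for the 17 genes with symbols that passed the test, ordered from the highest to the lowest log2 fold change, with 1 point per library (orange, 21 °C; blue, 5 °C) and a line at each group mean. The groups do not overlap for any of the 17 genes, as for nearly all called features, and the fold change of the edgeR fit runs from 1.19-fold (groEL_1) to 3.53-fold (prpE).

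The remaining 18 genes with symbols did not pass the test. For 16 of them the 95% confidence interval of the log2 fold change excluded a 2-fold change in either direction, and the exceptions were ubiA (0.64, 0.04 to 1.25) and glnQ (0.12, -0.76 to 1.01). The aconitase gene acnA measured 2953 ± 68.1 CPM at 21 °C and 2972 ± 499 at 5 °C, and kgd, for 2-oxoglutarate decarboxylase, 3079 ± 81.2 and 3170 ± 20.1. The chaperone genes dnaK and groEL_2 had log2 fold changes of 0.16 ± 0.09 and -0.14 ± 0.10. The ectoine synthase gene ectC, whose product makes a compatible solute, had -0.12 ± 0.11, with 653.9 ± 30.3 and 601.8 ± 38.0 CPM. The other genes without a call were hisE (0.38), carB (-0.26), obgE (-0.25), gltD (-0.25), truB (-0.16), glmU (0.10), thrS (-0.09), prfB (0.08), pyrH (0.06), rph (-0.03) and sufC (0.01). The gene hisE was called in 3 of 15 alternatives, 1 of them without replicate 1 at 5 °C, where its log2 fold change was 0.61. The gene ubiA was called in 1 of 14, without replicate 2 at 5 °C, where its log2 fold change was 1.01.

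Of the 31 gene lists fixed before the data were examined, 6 matched 9 genes by symbol, and 15 matched 24 genes once the usual product of each symbol was also searched, a step added after the values were seen. In the list of purine and pyrimidine synthesis, guaA and purH rose, and carB (-0.26 ± 0.12) and the uridylate kinase gene pyrH (0.06 ± 0.24) did not pass. Both members of the glycolysis list, pgk and eno, rose. Of 3 aminoacyl-tRNA synthetase genes, valS rose, ileS fell and thrS (-0.09 ± 0.11) did not pass. Of 3 chaperone genes, groEL_1 fell and dnaK and groEL_2 did not pass. In the list of translation factors fusA rose and the release factor gene prfB did not pass. The lists of ribosomal proteins and of ATP-dependent proteases held 1 gene each, rpsA and clpP, which rose. Those of cell wall and division and of iron acquisition held murD and fecE, which fell. The single members of 6 more lists did not pass: acnA (TCA cycle), ectC (compatible solutes), rph (RNA helicases and ribonucleases), truB (tRNA and rRNA modification), glnQ (amino acid transport) and ubiA, a prenyltransferase of quinone synthesis that matched the isoprenoid list. Adjusted over the list alone, the calls were those over all genes tested, with carB and ubiA in addition. Only the purine and pyrimidine list had the 4 tested members needed for a set test. It did not pass (limma's camera, p = 0.303 with the preset correlation and 0.633 with an estimated one). Therefore no statement is made about any of these pathways as a group.

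Among features without symbols, the largest falls by the rule for named genes lay close together on contig 23. BG28_RS12420, at 155671 to 157101, fell 13.6-fold from 993.2 ± 50.4 to 73.5 ± 9.62 CPM (-3.76 ± 0.16, edgeR adjusted p = 7.05e-35). BG28_RS12430, at 157951 to 159338, fell 10.9-fold from 582.3 ± 20 to 53.4 ± 4.85 (-3.44 ± 0.19, edgeR adjusted p = 1.04e-27). The largest rises by that rule were of BG28_RS01365, on contig 1 at 279993 to 281360, 3.61-fold from 95.7 ± 1.39 to 347.8 ± 28.4 (1.85 ± 0.19, edgeR adjusted p = 1.33e-13), and of BG28_RS13075, on contig 25 at 63604 to 65078, 3.34-fold from 258.8 ± 22.3 to 858.2 ± 126 (1.74 ± 0.13, edgeR adjusted p = 1.43e-20). All 4 passed under each of the 15 alternative settings tested on single genes, and all 4 changed by more than 2-fold. In all, 341 features without a symbol that rose and 213 that fell met the same conditions.

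The 2 falls on contig 23 belonged to a run of 9 consecutive tested genes from 155671 to 167733 that were all lower at 5 °C, with a median log2 fold change of -3.76 (range -4.39 to -1.83). The nearest tested gene on the side of lower coordinates measured 0.02 (95% confidence interval -0.33 to 0.37) and the nearest on the other side 0.21 (-0.01 to 0.42). The features at 155671 to 157101 and 157082 to 157765 overlap, so reads in the overlap cannot be assigned to either one. All 9 genes kept their calls with each library left out in turn. In the whole genome, 15 runs of 5 or more consecutive tested genes were lower at 5 °C, holding 102 genes, and 5 runs were higher, holding 30 genes. The minimum of 5 genes was chosen after the data were seen. Without replicate 1 or replicate 2 at 21 °C, or replicate 1 or replicate 2 at 5 °C, the falling runs numbered 11, 11, 9 and 8 and the rising runs 2, 1, 2 and 1. Other falling runs lay on contig 38 at 1 to 9683 (5 genes, median -3.0), on contig 14 at 108948 to 117050 (8 genes, median -2.57), on contig 24 at 25313 to 39528 (7 genes, median -2.01), on contig 5 at 106113 to 117609 (12 genes, median -1.89) and on contig 3 at 49120 to 54085 (6 genes, median -1.56). The rising run with the largest median lay on contig 25 at 88772 to 95115 (5 genes, median 2.21), followed by contig 42 at 5038 to 8850 (5 genes, median 1.14). The longest rising run, 9 genes on contig 1 at 169773 to 184158, held fusA and had a median of 0.39. A minimum mean of 50 reads left thinly covered genes untested and lowered the count of called genes in several runs. It left 4 of 9 in the run at 155671 on contig 23, 3 of 5 on contig 38 and 3 of 8 at 108948 on contig 14. On contig 24 it left 0 of 7, at 106113 on contig 5 it left 3 of 12, and on contig 25 it left 1 of 5. The run on contig 3 kept 5 of 6. With a library left out, the fewest called genes were 7 of 8 in the run at 108948 on contig 14 (without replicate 1 or replicate 2 at 5 °C), 3 of 7 on contig 24 (without replicate 1 at 5 °C) and 10 of 12 on contig 5 (without replicate 1 at 5 °C). They were 3 of 5 on contig 25 (without replicate 2 at 21 °C, or replicate 1 or replicate 2 at 5 °C) and 5 of 9 in the run with fusA (without replicate 2 at 5 °C), which held 2 of 9 without a composition factor and whose median fell to 0.15 at the lowest over the alternatives. The runs on contigs 38, 3 and 42 kept every call. Of all 20 runs, 5 kept every call, and the falling run on contig 4 at 168973 to 177191 held 2 of 5 without replicate 1 at 5 °C.

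**Figure D2:**
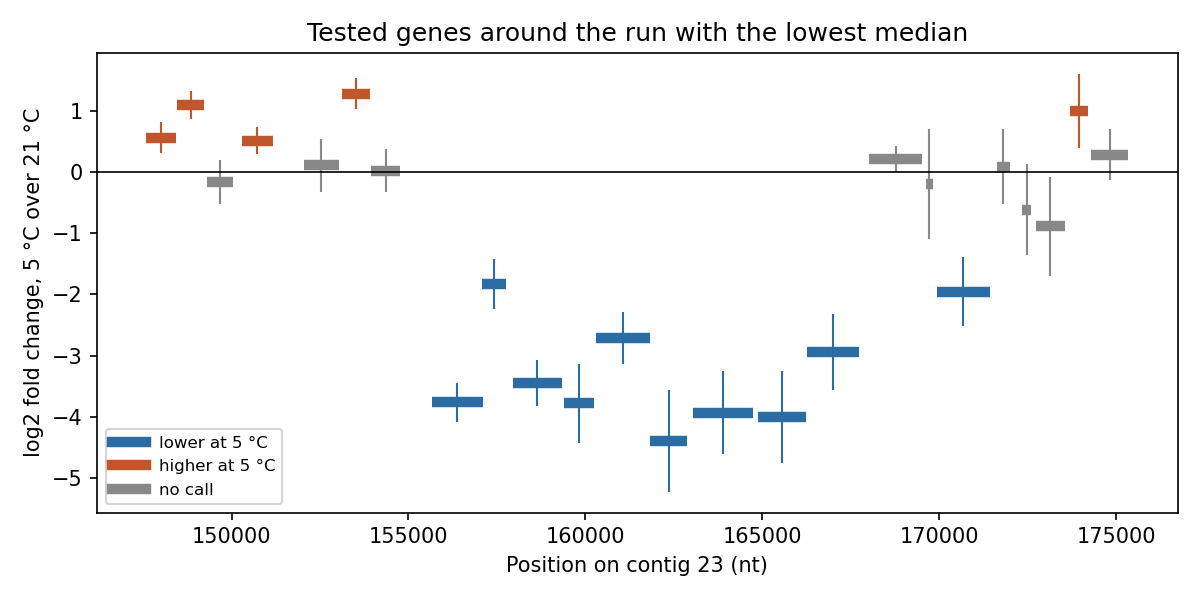
log2 fold change (5 °C over 21 °C, vertical axis) of tested genes against position in nt on contig 23 (horizontal axis), with each gene drawn as a bar from its start to its end and a thin line for its 95% confidence interval. The 9 genes between 155671 and 167733 lie between -4.39 and -1.83, and the tested genes next to them on either side lie at 0.02 and 0.21.

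In the test of all genes (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 451 of 2336 tested features were higher and 472 lower at 5 °C. The features that fell changed more than those that rose, with a median of 2.0-fold against 1.55-fold, and they held fewer reads, a median of 44.25 against 121.5 per library. A change of 2-fold or more was measured for 87 that rose and 234 that fell, and of 4-fold or more for 8 and 68. Among the 1149 features with a mean of 50 or more reads, 46 rose and 49 fell by 2-fold or more. The split between directions depended on the scaling: 48.9% of the calls were rises with composition factors, and 37.4% (257 rises, 431 falls) without them. DESeq2 called fewer genes, 206 higher and 181 lower, and leaving out replicate 2 at 5 °C lowered the count of falls to 309. The authors' deposited table gives 455 genes higher and 460 lower in its EDGE test and 374 and 378 in its Baggerley's test, at an adjusted p under 0.05. Of the calls made here, 854 were also made in one direction by the EDGE test of the authors' deposited table and 660 by its Baggerley's test, with 0 in opposite directions. The EDGE test made 61 calls not made here. It lacked 69 made here, among them aspA, groEL_1 and ileS (EDGE adjusted p = 0.175, 0.118 and 0.0595). Baggerley's test did not call argD, clpP, fusA, purH, rpsA and valS (its adjusted p from 0.0558 to 0.369). It called carB, groEL_2 and kgd lower (0.0116, 0.000103 and 0.00269), which had no call here.

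**Figure D3:**
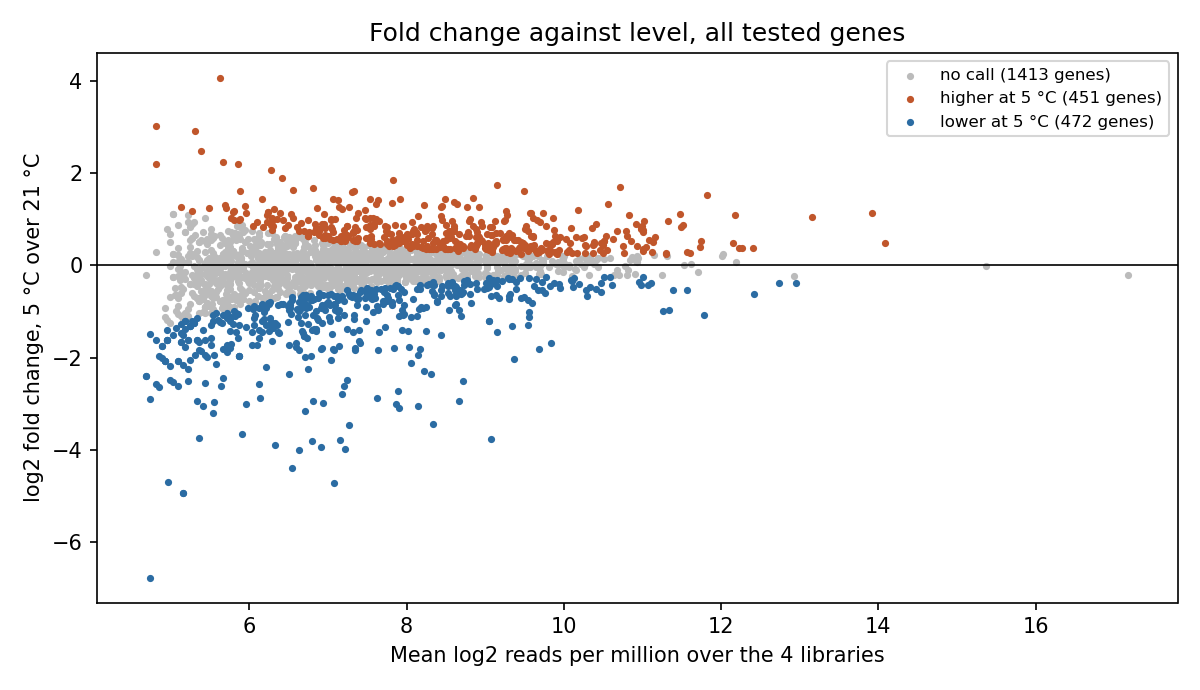
log2 fold change (5 °C over 21 °C, vertical axis) against mean log2 CPM over the 4 libraries (horizontal axis) for the 2336 tested features, with features higher at 5 °C in orange (451), lower in blue (472) and without a call in grey. The falls reach a log2 fold change of -6.77 and the rises 4.07.

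Replicates were closer to each other than to the libraries of the other temperature. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.975 between the 21 °C libraries and 0.977 between the 5 °C libraries, against 0.892 to 0.901 between temperatures. A chi-square of the counts left out the 2 features with the most reads and features with few reads in the pair. Per degree of freedom it was 1.25 and 1.29 within the groups, so replicates differed beyond sampling noise, and 9.71 to 10.5 between them. The 2 features left out took 13.8% and 26.2% of the gene reads at 21 °C and 14.7% and 19.9% at 5 °C. Their difference between replicates is therefore not in these values.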

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

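Total gene reads, on which the comparison of temperatures was run, exceeded unique gene reads in each library. The excess was 583 and 559 reads at 21 °C and 812 and 666 at 5 °C. Whether any of these reads was counted for more than 1 feature was not tested. No gene with a symbol held such reads, and the counts of genes called from unique reads were 454 higher and 474 lower at 5 °C.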

How the results depend on the processing

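The fits without the 2 features with the most reads and on the quantile-normalized values, the count of runs and the matching of lists to products were chosen after the result was seen. Of the 2 counts of called genes, the count of rises (451) moved beyond 1.5 times without a composition factor (257), in DESeq2's Wald test (206), with a mean of 50 or more reads (275), with an added 2-fold threshold (87) and in limma on log2(RPKM + 1) (206). The count of falls (472) moved in DESeq2's Wald test (181), with a mean of 50 or more reads (291) with the 2-fold threshold (234) and without replicate 2 at 5 °C (309). The minimum of 50 reads left 1149 genes to test, and 275 of its rises and 217 of its falls were among the calls of the full test, while it shifted the median log2 fold change by -0.10. The median dispersion was 0.0430 in DESeq2 and 0.00258 in edgeR, and the cause of that gap was not tested. Nor was the cause tested for the RPKM and composition settings, which divide by library totals. Those totals include the 2 features with the most reads, with 13.8% and 26.2% of the gene reads at 21 °C and 14.7% and 19.9% at 5 °C. With each library left out, rises numbered 325 to 369 and falls 309 to 382, the fewest without replicate 2 at 5 °C, where the lone library of a group is assumed to vary like the other group's. limma-voom (440 and 458), DESeq2 size factors (481 and 464) and quantile-normalized values (371 and 365) stayed within 1.5 times. Of 21 named genes with a call, 7 kept it at an adjusted p under 0.05 in each alternative that tested them, guaA, pgk, prpE and the 4 features without symbols; 14 lost it in some, and 0 changed direction. An added 2-fold threshold left 6 of the 21, prpE, argD and those 4 features. On the quantile-normalized values fusA and rpsA shrank to 0.17 and 0.09 from 0.48 and 0.37. Of 18 without a call, 7 gained one somewhere, among them kgd, which turned negative on the quantile-normalized values (-0.19, limma adjusted p = 0.0168; the cause was not tested), and groEL_2 on the same values (-0.34, limma adjusted p = 0.000815). Runs of genes lower at 5 °C numbered 4 to 17 and runs higher 0 to 6 over the alternatives, against 15 and 5, with 9 and 8 falling runs without replicate 1 and replicate 2 at 5 °C. The set test of the purine and pyrimidine list passed in 0 of its alternatives (limma p = 0.161 to 0.633 over fry, an estimated correlation, 2 scalings and each library left out); with a mean of 50 or more reads it had too few members to run. No separate fit was run for the planned retention of ribosomal RNA genes. No feature is marked as one, and the main fit left none out. Of simulated changes, 41.5% at 1.5-fold and 70.1% at 2-fold were recovered, so small changes were missed more often. The simulation did not vary depth or the number of libraries, so the share of depth in this was not tested. It changed 200 genes, against 923 called in the data.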

Other observations

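The tests of scaling, of subtracted background, of a random order of genes, of shuffled blocks, of overlapping pairs, of small contigs and of better-covered features from 100 nt to under 300 nt were chosen after the result was seen; the others were set before. Around ectC on contig 15, the neighbours at 37317 to 38603 and 39381 to 40529 were lower at 5 °C, by log2 fold changes of -0.62 ± 0.11 and -1.09 ± 0.13 (edgeR), while ectC itself had -0.12 ± 0.11 and no call. Next to fecE on contig 3 the feature at 26714 to 27719 was lower (-1.21 ± 0.24). The features beside pgk at 15410 to 16414 and 16736 to 17359 were higher (0.34 ± 0.09 and 0.82 ± 0.10), as was that beside glpK at 3615 to 4361 (0.61 ± 0.14). Neighbours also went the other way: the feature at 1 to 805 near glpK was lower (-1.45 ± 0.35), those at 32589 to 33761 and 36503 to 38026 near groEL_1 were higher (0.68 ± 0.13 and 0.76 ± 0.15), and so was that beside murD at 72154 to 73221 (0.56 ± 0.14). These neighbours kept their calls with each library left out in turn. Within 3 features of the 17 called genes with symbols, 24 pairs of a named gene and a called neighbour shared a direction and 14 did not. A neighbour of more than 1 named gene is counted for each. The feature at 105990 to 107717 on contig 19, for example, went with ileS and against valS. Several of the pairs that shared a direction lay around fusA, inside its rising run. On contig 38 all 5 tested genes were called lower at 5 °C (median -3.0). On contig 39 all 9 had negative log2 fold changes and 5 of them passed (median -0.68). On contig 35 all 5 had positive ones and 0 passed (median 0.17). Among contigs with 3 or more tested genes, only 13, 32, 33 and 36 also had a single sign. Their 5, 3, 3 and 3 tested genes all had negative log2 fold changes. Across the 2336 tested genes, which are not independent replicates, Spearman's rho of log2 fold change with level was 0.26, and of 4 classes of 584 genes by level the lowest held 27 rises and 130 falls against 235 and 111 in the highest.

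Features under 100 nt were lower at 5 °C: of 12 tested, 8 fell and 0 rose, with a median log2 fold change of -1.19, and with a library left out 6 to 8 fell and 0 rose. The 48 such features summed to 2869 ± 107 CPM at 21 °C and 1091 ± 138 at 5 °C, 2.63-fold less, and still 2.19-fold less without the 73 nt feature on contig 19 that held the most of these reads. Few reads alone would leave the better-covered short features near 0, but the 3 with a mean of 50 or more reads had a median of -1.40 (range -1.81 to -1.0). Loss of short molecules in preparing the 5 °C libraries stays open: over all tested features from 100 nt to under 300 nt the median differed from that of longer ones by 0.0617 (95% bootstrap interval -0.0538 to 0.167), above the bound of -0.293 set beforehand, but that median rests largely on thinly covered features. With a mean of 50 or more reads the difference was -0.15 (-0.36 to -0.03), which spans the bound, and the summed CPM of the class went from 48142 ± 1544 to 40015 ± 477, a log2 difference of -0.34 from longer features; a lower level of short transcripts in cold-grown cells was not tested separately.

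Falls of 2-fold or more outnumbered such rises, 234 against 87, and 184 to 230 against 89 to 100 with a library left out. Additive background such as genomic DNA at 21 °C stays open. The level of the least expressed genes (lowest 5% of features of 500 nt or more) was 19.1 RPKM at 21 °C and 7.07 at 5 °C, which goes with it. With the excess of 11.99 RPKM subtracted from every tested gene at 21 °C there were 189 falls and 105 rises, a ratio of 1.80 (95% interval 1.41 to 2.31), and with 19.1 RPKM subtracted 166 and 125, a ratio of 1.33 (1.05 to 1.69). Both intervals span the bound of 1.5. The intervals of these ratios take genes as independent, although neighbouring called genes often shared a direction, and do not cover variation between cultures. The test set beforehand, the share of the 234 falls that lost more than 19.1 RPKM, decides nothing, because passing the call nearly fixes it: the share was 98.3%, and 100% of the rises gained more than that. Over 4 scalings the smallest ratio of falls to rises was 2.53. Against the main fit, DESeq2 size factors, upper-quartile scaling and no composition factor moved the median log2 fold change by only 0.015, -0.036 and -0.060. A larger error of scaling can therefore not be excluded by them. Few reads per gene cannot be told apart from a real difference: among the 1149 genes with a mean of 50 or more reads there were 49 falls and 46 rises, a ratio of 1.07 (95% interval 0.70 to 1.63) that leans to a pattern confined to thinly covered genes, but spans the bound of 1.5. Temperature remains an untested biological explanation.

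Called genes lay next to genes called in the same direction: 80.3% of 431 adjacent called pairs shared a direction, against at most 60.3% in 1000 shuffles of gene order, so a random order is argued against. For contigs with 20 or more tested genes, whole contigs moving together are argued against, since 79.6% of 402 pairs shared a direction after each contig's median was subtracted, with at most 60.8% in shuffles within contigs; on smaller contigs this stays open (72% of 25 pairs, at most 87.5% in shuffles). Reads counted for overlapping or touching neighbours do not account for the pairs more than 300 nt apart, and so not for the whole pattern. Of 100 such pairs 67% shared a direction (exact 95% interval 56.9% to 76.1%), wholly above the median of 50% in 10000 shuffles that kept closer genes together as blocks, and 14 of these shuffles came as high (one-sided p = 0.0015). With a library left out the share was 70% to 73.2%, of 41 to 60 pairs. The bound set beforehand, the maximum of 1000 shuffles of single genes, was set aside after the value was seen because it moves with the draw: the first gave 70.6%, which counts for overlap, although 2 of its 1000 shuffles reached 67%. Over 100 further draws the maximum ran from 64.5% to 76.8%, and in 24 it lay below 67%, which argues against overlap. Among closer pairs the values go with reads counted for overlapping neighbours. Of 52 overlapping pairs 96.2% shared a direction, against 82.1% of 279 pairs 0 to 300 nt apart. The difference was 14.1 percentage points (95% interval 6.0 to 22.1, with pairs taken as independent). Reads inside overlaps were not counted, so whether they are enough to give this difference is not known. Transcription of neighbours as units, which was not tested, could give the same difference.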
